A study of Homo sapiens with 47 samples.

How the data were processed

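RNA from 2 human colon cancer cell lines, HT29 and SW480, was measured on Illumina 1-colour beadchip arrays with a Cy3 label, per the labels. The arrays held 46752 probes, and 47 arrays on 4 slides were analysed. The labels place the arrays in 16 groups, by line (HT29 or SW480), construct (mock or estrogen receptor beta, ERb), treatment (vehicle or 10 ng/mL TNFa) and time (2 or 24 h). They write the constructs as mock2 and ERb2, and do not say what the 2 stands for. Each group had 3 arrays, except SW480 mock cells with vehicle for 2 h, which had 2 (replicates 1 and 3). HT29 arrays lay on slides 1 and 2, SW480 arrays on 3 and 4. Each group had 1 or 2 arrays on each of its line's slides. No 2 arrays held identical signals.

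Per the file headers, the deposited scanner table gives an intensity per probe and array, not normalized. No background had been subtracted, since no value was near 0. The same table gives, per the file headers, a detection p-value per probe and array, which sets each signal against the negative control beads. A second deposited table holds the authors' processed values on a log2 scale. All of its columns shared their sorted values, so the authors' log2 values were quantile normalized over all arrays; the median of the array medians was 5.93, and their rank correlation (Spearman) with the intensity of the same array was 1. The submitters' processing notes name limma, version and steps not given. The authors' log2 values served only as an alternative.

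Intensities were background corrected with limma's neqc, which took the negative control mean and spread from the detection p-values, used an offset of 16, quantile normalized all arrays together and took log2. Of the probes, 29811 had 1 gene symbol in the platform annotation, 8 had several and 16933 had none listed. Symbols of 29772 probes were checked by Entrez gene number against a RefSeq gene table. Each of 19904 genes was represented by its probe with the highest mean over all arrays, and other probes of a named gene that moved differently are pointed out. A gene was tested in a line when its probe had a detection p under 0.05 on at least 3 arrays of that line. That gave 12354 genes in HT29, 13109 in SW480 and 13907 in either line for differences between the lines. Genome positions were not used, as the annotation names only genes.

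Linear models were fitted to group means with limma (lmFit and eBayes), over all arrays of a line, or over all arrays of both lines for differences between the lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p for a gene comes from limma, and all tests are two-sided except Fisher's exact tests of overlap, which are one-sided. Where no probe of a gene was above background on any array of a group, the fold is given as "at least", from the brighter group's mean against a floor. That floor was, per array, the higher of the lowest signal among detected probes and the probe's own signal. The comparisons were TNFa against vehicle in each line, construct and time, ERb against mock cells with vehicle (mean of both times), the difference of TNFa effects between ERb and mock cells (the interaction), and the difference of effects between times and between lines.

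There were 19 gene lists. Of these, 17 had at least 5 measured members in each line: NF-kB target, interferon response, antigen presentation, immediate early, cell cycle, p53 and apoptosis, estrogen-responsive, Wnt target, intestinal epithelial differentiation, epithelial adhesion, mesenchymal, unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, circadian clock, heat shock and immune cell marker. The fibroblast and endothelial marker lists had too few measured members to test. For the interactions, genes that rose or fell with TNFa in mock cells of the other line were tested as further lists. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Counts "adjusted over the list alone" are adjusted over the measured members of that list.

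Named genes followed a rule. It took ESR2 in every group and, in TNFa comparisons and interactions, a panel of 12 genes (NFKBIA, TNFAIP3, BIRC3, RELB, NFKB2, CXCL8, CXCL1, CCL20, ICAM1, SOD2, IL6 and TNF). It added the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap (5 and 5 called genes for differences of effects), and up to 4 called members per list. Genes on the Y chromosome and XIST were never named, nor were probes without exactly 1 symbol. The groups, the comparisons, the tests, the gene lists, this rule and the alternatives were fixed before the data were examined, apart from leaving 1 low-signal array out of comparisons that do not hold it and the comparison of vehicle groups between times, which were added later.

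The alternatives were no background correction, the authors' values, each line normalized apart, no filter on detection, every probe tested, only the arrays compared, all arrays of both lines in one fit, the slide as a block, the replicate number as a block, leaving out each array in turn, and for the overlaps between lines a threshold of 0.01. The labels do not say what replicate numbers stand for. Over 31 pairs of same-numbered arrays, deviations from the group means correlated by 0.199 to 0.788 (median 0.549), and in all 31 each number was closest to its own. These leave out HT29 mock cells at 24 h, where the low-signal array lies: there the 3 pairs had 0.375, 0.37 and 0.199, the last under the 0.212 with another number, and without that array 2 pairs had 0.351 and 0.317. Numbers were thus taken to pair samples, but the main fits were unpaired.

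The methods were tested on simulated data with the spread of the real arrays. With 100 genes changed by a log2 of 1, 40% were recovered for TNFa at 24 h in HT29 mock and 67% in SW480 mock cells. With a log2 of 2 these shares were 83% and 99%. For the interactions at 24 h, 17% of genes changed by 1 and 54% of genes changed by 2 were recovered in HT29, and 27% and 85% in SW480. With the spread of HT29 arrays other than the low-signal array, the HT29 interaction shares were 56% and 94%. The number of arrays limits the precision of all values. Computation used R 4.3.3 with limma 3.58.1 and version 1.17.8 of the package data.table.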

Results

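The series follows 2 human colon cancer cell lines, HT29 and SW480. Each line carried either a mock construct or a stable construct for estrogen receptor beta (ERb), a nuclear receptor encoded by ESR2. Cells were given vehicle or 10 ng/mL tumour necrosis factor alpha (TNFa), an inflammatory cytokine that activates the transcription factor NF-kB, and RNA was taken after 2 or 24 h. The series title names the question as how ERb modulates NF-kB signalling in these lines. The 47 arrays fell into 16 groups of 3, except SW480 mock vehicle cells at 2 h (2). Probes detected per array numbered 18239 to 19843 in HT29 and 17848 to 20749 in SW480, apart from 1 HT29 array (mock, TNFa, 24 h, replicate 1) with 12776. That low-signal array had a mean correlation of 0.675 with the other HT29 arrays, which had 0.953 to 0.968 among themselves. It was kept, and counts without it (chosen after seeing the data where it is not among the arrays compared) are given where they differed by more than 1.5 times. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values after gene names are log2 differences with a standard error (SE) from limma, over 3 arrays against 3 unless stated.

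ESR2 is the gene of the construct. In mock cells its mean log2 signal was 4.70 to 4.92 in HT29 and 4.68 to 4.75 in SW480, and it was above background on 1 mock array only, an HT29 array with TNFa at 2 h (5.47). In HT29 ERb cells it averaged 6.45 ± 0.212 (SD, n = 3) with vehicle at 2 h, 9.98 ± 0.317 with TNFa at 2 h, 5.50 ± 0.0464 with vehicle at 24 h and 7.38 ± 0.081 with TNFa at 24 h. In SW480 ERb cells the same groups averaged 6.98 ± 0.28, 8.57 ± 0.485, 6.34 ± 0.288 and 7.16 ± 0.194 (SD, n = 3). Without TNFa, ESR2 was higher in ERb than in mock cells by 1.20 in HT29 (SE 0.155, at least 1.71-fold, adjusted p = 0.000338, 6 arrays against 6) and by 1.92 in SW480 (SE 0.159, at least 2.8-fold, adjusted p = 4.52e-07, 6 against 5). A second, dimmer ESR2 probe did not call these (0.37 and 0.78, adjusted p of 0.815 and 0.086). The first probe gave 1.595 and 0.80 in HT29 at 2 and 24 h (adjusted p of 0.00161 and 0.817). In SW480 both times were called.

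**Figure D1:**
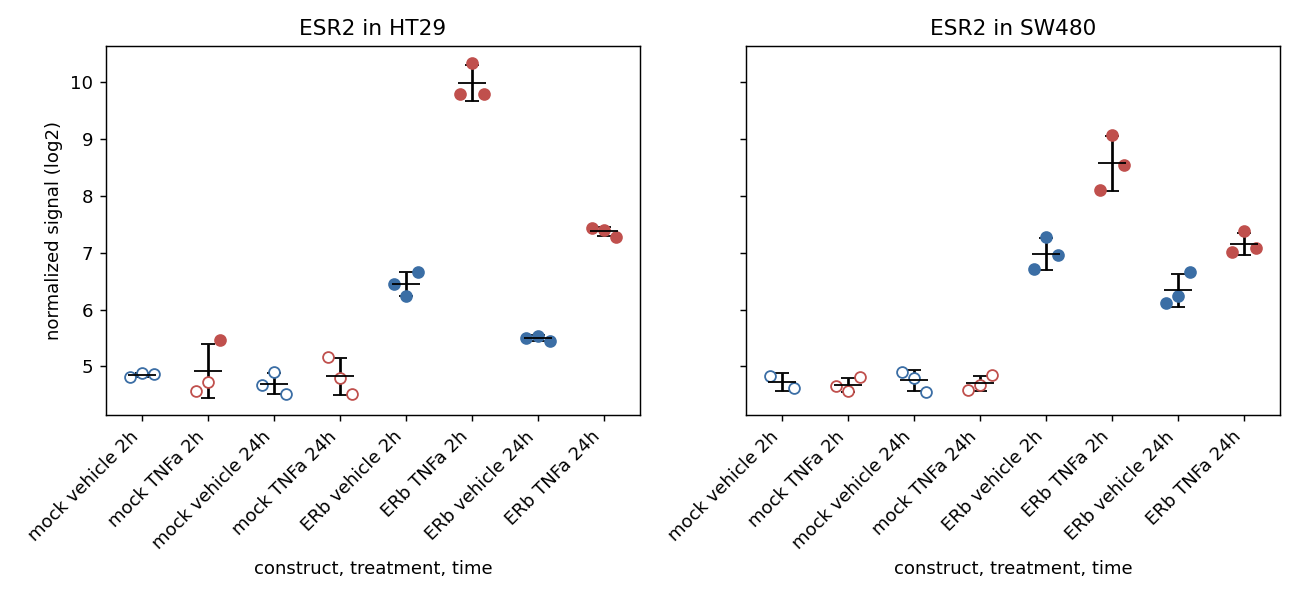
ESR2 signal (log2, normalized) on each array by line, construct, treatment and time; points are arrays (open where not above background), bars are means with SD, vehicle in blue and TNFa in red. Mock groups averaged 4.68 to 4.92, and the highest group, HT29 ERb cells with TNFa at 2 h, averaged 9.98.

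TNFa raised the ESR2 signal of ERb cells, at 2 h in both lines and at 24 h in HT29. In HT29 ERb cells it rose 11.6-fold at 2 h (3.53, SE 0.219, adjusted p = 6.4e-09) and 3.67-fold at 24 h (1.88, adjusted p = 4.98e-05), and in SW480 ERb cells 3.01-fold at 2 h (1.59, SE 0.211, adjusted p = 0.000284). At 24 h in SW480 the difference was 0.82 (SE 0.211, adjusted p = 0.163, and 0.0377 with the replicate block). Within slides HT29 had 3.73 and 3.14 at 2 h and 1.93 and 1.85 at 24 h. SW480 had 1.6 and 1.58 at 2 h and 0.904 and 0.78 at 24 h. The second probe gave 3.66 and 1.49 in HT29, and 1.45 and 0.93 in SW480 (adjusted p of 0.00942 and 0.294).

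In HT29 mock cells, TNFa for 2 h raised genes of chemokines and of NF-kB regulators. The chemokine genes CCL20 (6.08, SE 0.578, 67.8-fold), CXCL1 (5.15, SE 0.339, 35.4-fold) and CXCL8 (4.95, SE 0.603, 30.9-fold) rose most among genes that were above background with vehicle. CXCL2, another neutrophil chemokine, rose at least 21.4-fold, and TNF itself at least 18.3-fold (4.95, SE 0.207, adjusted p = 7.72e-12). NFKBIA, which encodes the inhibitor IkB alpha, rose 13-fold (3.70, SE 0.136, adjusted p = 1.54e-12), and TNFAIP3, which encodes the inhibitor A20, rose at least 25.2-fold (4.84, SE 0.384). The NF-kB subunit genes RELB (3.30, SE 0.371) and NFKB2 (3.25, SE 0.662, adjusted p = 0.0152) and the adhesion molecule gene ICAM1 (3.83, SE 0.363, 14.2-fold) rose as well, as did TNFAIP2 (4.33, SE 0.32). SOD2, a mitochondrial superoxide dismutase, differed by 1.31 (SE 0.334, adjusted p = 0.0933, but 0.00568 with the replicate block, 0.00909 with the slide as a block and 0.00113 without the low-signal array). The largest falls were PRR15L (-1.95, SE 0.3), SLITRK6 (-1.65, at least 2.17-fold) and ZNF792 (-1.52).

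Of 46 measured NF-kB targets, 31 rose in HT29 mock cells at 2 h and 0 fell (37 and 0 adjusted over the list alone), with a median of 2.71 (camera adjusted p = 1.46e-139, and 1.35e-09 with an estimated correlation). Of 26 immediate early genes, which encode rapidly induced transcription factors and regulators, 6 rose (10 over the list alone), among them DUSP5 (1.57), JUNB (1.39), FOSL1 (1.32) and ATF3 (1.31, other probes near 0). That list's median was 0.594 (adjusted p = 5.28e-14, and 0.000159 with an estimated correlation). The p53 and apoptosis list also moved up (29 measured, 3 higher, median 0.196, adjusted p = 1.56e-05, and 0.000492 with an estimated correlation). Over the list alone 6 of its genes were higher and 2 lower. Its called members were the cell cycle inhibitor CDKN1A (2.57, another probe 0.494), the death receptor TNFRSF10B (1.51) and the BH3-only gene PMAIP1 (1.49). The stress gene PPP1R15A (1.59) and the growth factor VEGFA (0.87, 1 of 2 other probes not following) were the only called members of the unfolded protein response and hypoxia lists. Interferon response (median 0.251, adjusted p = 0.0257) and antigen presentation (0.289, adjusted p = 0.00123) passed camera with 0 called genes, but their adjusted p was 0.733 and 0.334 with an estimated correlation.

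In all, 98 genes rose and 12 fell in HT29 mock cells at 2 h, and 86 and 6 of these changed at least 2-fold. Without the low-signal array, which entered only through the shared estimate of the spread, 271 rose and 213 fell. The slide block gave 113 and 18. Arrays of all 110 genes did not overlap, which fixes their sign within slides. Median sizes there were 1.83 and 1.54, and NF-kB medians 2.66 and 2.44.

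After 24 h in HT29 mock cells LTB, which encodes the cytokine lymphotoxin beta, rose at least 98.2-fold (7.35, SE 0.534), the cytokine gene IL32 at least 43.6-fold (5.85, SE 0.369), the ubiquitin-like modifier UBD at least 26.4-fold (5.29, SE 0.404) and PI3, an elastase inhibitor of epithelia, 38.4-fold (5.26, SE 0.302, adjusted p = 1.35e-09). The interferon-inducible genes CXCL10 (24.2-fold) and UBE2L6 (4.37, SE 0.838, other probes lower) rose too. NFKBIA (2.59, SE 0.136), TNFAIP3 (2.88, at least 5.4-fold), CXCL1 (2.85), CCL20 (4.67), TNF (4.02, at least 9.68-fold) and ICAM1 (2.02, at least 3.47-fold) were still raised, together with RELB (3.89), NFKB2 (4.21) and CXCL8 (31.9-fold, SE 0.603 on the log2 scale). SOD2 differed by 0.79 (adjusted p = 0.207, and 1.31 with adjusted p = 0.00432 without the low-signal array). Falls included REG4, a secreted lectin of intestinal epithelium (-3.30, SE 0.624), the neurotrophin BDNF (-2.70, SE 0.468, its 6 other probes not following), POU2AF3 (-2.31, at least 3.07-fold), the scaffold protein PDZK1 (-2.28, at least 3.12-fold) and coagulation factor F5 (-2.17).

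The NF-kB list stayed up in HT29 mock cells at 24 h (21 rose, 0 fell, 30 and 1 over the list alone, median 1.28, adjusted p = 4.13e-27, and 0.000131 with an estimated correlation). Of 42 interferon response genes 13 rose and 0 fell (34 and 0 over the list alone), with a median of 1.95 and an adjusted p of 2.02e-22. For that list the adjusted p = 0.12 with an estimated correlation, and 0.0182 with the replicate block as well. Its called members included the antiviral genes OAS2 (4.15, SE 0.926), MX2 (3.83) and EPSTI1 (3.68). Antigen presentation rose (19 measured, 7 higher, 11 over the list alone, median 1.27, adjusted p = 3.35e-09, and 0.0308 with an estimated correlation), through the immunoproteasome subunit PSMB9 (4.09, another probe 1.59), HLA-B (3.19), the peptide transporter TAP1 (2.48) and TAPBP (2.05, other probes lower). The p53 and apoptosis list moved up by a median of 0.332 (adjusted p = 0.00556, and 0.0254 with an estimated correlation), with CDKN1A (1.94, another probe -0.0573), PMAIP1 (1.47) and the death ligand TNFSF10 (2.27) called. Of the immediate early genes 1 rose, NR4A2 (0.93). Of 21 intestinal differentiation genes 2 fell (5 over the list alone), among them the brush border peptidase DPP4 (-1.37). That list's median was -0.651 (adjusted p = 0.00391, then 0.199 with an estimated correlation). Of 23 estrogen-responsive genes 2 fell (1 higher and 3 lower over the list alone), AGR2 among them (-1.53), with an adjusted p of 0.408 for the list. The immune cell marker list had 1 of 7 genes called, the integrin gene ITGAM (2.03).

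At 24 h in HT29 mock cells 140 genes rose and 55 fell (128 and 41 at least 2-fold). These counts were 278 and 163 with the replicate block, 195 and 88 with the slide block and 244 and 94 without the low-signal array. They were only 6 and 0 with the arrays compared alone, and 418 and 598 with all arrays of both lines in one fit. Without that array OAS2, TNFSF10 and AGR2 had adjusted p of 0.0592, 0.0636 and 0.0556. Here slide 1 held only the low-signal and 1 vehicle array. By slide, called genes had median sizes of 2.3 and 1.38. List medians were 1.03 and 1.44 for NF-kB and 1.66 and 2.09 for interferon response. They were 1.91 and 0.868 for antigen presentation and -0.988 and -0.571 for intestinal differentiation. The circadian clock median was -0.204 while camera pointed up (adjusted p = 0.945).

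SW480 mock cells with TNFa for 2 h (3 arrays against 2) raised many of the genes seen in HT29. CCL20 rose 31.4-fold (4.97, SE 0.517, adjusted p = 2.03e-05), CXCL1 17.8-fold (4.15, SE 0.651), TNFAIP3 17.6-fold (4.14, SE 0.373) and CXCL8 14.7-fold (3.88, SE 0.614). NFKBIA (2.70, SE 0.225), RELB (2.85, SE 0.206), NFKB2 (2.64, at least 5.2-fold) and TNF (3.11, at least 5.22-fold) rose, and so did BCL3, an IkB family member (4.48), UBD (3.99) and TNFAIP2 (3.92, at least 10.4-fold). ICAM1 differed by 1.73 (at least 2.98-fold, SE 0.38, adjusted p = 0.0539, but 0.000844 with the replicate block and 0.00322 with the slide as a block), and SOD2 by 0.12. The only called fall was TAF3, a subunit of the general transcription factor TFIID (-0.93, adjusted p = 0.0434, another probe -0.0963). Of 46 NF-kB targets 25 rose (33 over the list alone) and 0 fell, with a median of 1.68 (adjusted p = 9.02e-115, and 2.09e-06 with an estimated correlation). Called members of other lists were JUNB (1.16), TNFSF10 (2.05) and CAV1 (0.78), a caveola protein on the mesenchymal list.

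Of 24 Wnt targets in SW480 mock cells at 2 h, 0 were called (1 lower over the list alone), but the list lay low as a whole (median -0.428, adjusted p = 1.29e-07, and 0.000807 with an estimated correlation). Antigen presentation lay slightly high (median 0.188, adjusted p = 0.000499, and 0.0372 with an estimated correlation). Other lists passed camera but not with an estimated correlation. They were interferon response (0.171, adjusted p = 0.0254, then 0.548), p53 and apoptosis (0.0489, adjusted p = 0.00741, then 0.171), immediate early genes (0.14, adjusted p = 0.0207, then 0.757) and cell cycle genes (-0.212, adjusted p = 0.00441, then 0.76). Under the replicate block the last 2 lists had adjusted p of 0.0972 and 0.0684. In all 50 genes rose and 1 fell (48 and 0 at least 2-fold), with 76 and 7 under the replicate block and 68 and 3 under the slide block, but 14 and 0 with only the arrays compared. Within slides the median sizes of called genes were 2.05 and 2.17, the NF-kB medians 1.76 and 1.83, and the Wnt medians -0.501 and -0.31. In HT29 mock cells at 2 h the Wnt list had an adjusted p above 0.05, and 0.0412 with the slide as a block (median -0.282).

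At 24 h in SW480 mock cells UBD rose 85.8-fold (6.42, SE 0.29, adjusted p = 5.73e-11), IL32 at least 20.1-fold (4.74, SE 0.298) and LTB at least 12.4-fold (4.17, SE 0.849). The chemokine genes CX3CL1 (2.87), CXCL6 (2.74) and CCL20 (2.44) rose, with TNFAIP3 (2.91), NFKBIA (1.83, SE 0.202), RELB (1.77) and NFKB2 (1.43). CXCL8 and CXCL1 differed by 2.19 (adjusted p = 0.147) and 1.97 (adjusted p = 0.374). With the replicate block both were called (adjusted p of 0.00712 and 0.00757). TNF (0.85), ICAM1 (-0.11) and SOD2 (0.07) were not called. Of the NF-kB list 11 genes rose and 0 fell (20 over the list alone, median 0.672, adjusted p = 4.4e-33, and 0.0015 with an estimated correlation). Antigen presentation rose (6 higher, 10 over the list alone, median 0.497, adjusted p = 3.35e-22, and 1.52e-05 with an estimated correlation), with PSMB9 (2.42, another probe 0.434), HLA-B (1.85), PSMB8 (1.78, 1 of 3 other probes lower) and TAPBP (1.62, other probes lower) called. Of 36 interferon response genes 1 rose, the RNA sensor IFIH1 (1.26), and 7 over the list alone (median 0.395, adjusted p = 3.61e-13, and 0.00342 with an estimated correlation). TNFSF10 rose (2.13, SE 0.393). The unfolded protein response list had a median of -0.193 (adjusted p = 0.00725, then 0.601 with an estimated correlation).

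In SW480 mock cells at 24 h 47 genes rose and 0 fell by limma (40 of them at least 2-fold), out of 597 with an unadjusted p under 0.05 (655 with no change). Counts with the replicate block were 123 and 7, and with the slide block 62 and 1. Within slides the called genes had median sizes of 1.85 and 1.36, and medians were 0.907 and 0.501 for NF-kB, 0.485 and 0.503 for antigen presentation and 0.449 and 0.4 for interferon response.

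The responses of the 2 lines overlapped. Among genes tested in both lines, 36 rose in both at 2 h (95 called in HT29 and 48 in SW480), against 0.395 for independent lists (Fisher's exact test, p = 2.84e-68). At 24 h 28 rose in both (131 and 43 called, 0.487 for independent lists, p = 2.06e-45 by Fisher's exact test). The difference itself, SW480 minus HT29, was called for 12 genes at 2 h, 4 positive and 8 negative. Prostaglandin synthase PTGS2 (-3.89, SE 0.493), FAM43A (-3.33), PI3 (-3.20), IER3 (-2.46) and the cytokine gene IL1B (-2.05) responded more in HT29. UBD (2.63) and NFKBIZ, an IkB family member (2.56, another probe -0.127), responded more in SW480, and PRR15L (2.32) and SLITRK6 (1.72), which had fallen in HT29, also differed positively. Each slide held 1 line, and with the slide as a block 5 genes were positive and 10 negative. The split of calls was 2 positive and 16 negative without background correction and 4 and 15 with the authors' values. The NF-kB list responded less in SW480 (49 measured, 1 positive and 4 negative calls, 2 and 10 over the list alone, median -0.449, adjusted p = 2.39e-13, and 0.0151 with an estimated correlation). Without the low-signal array the latter was 0.0573. The immediate early list had a median of -0.242 (adjusted p = 4.85e-05, then 0.189 with an estimated correlation).

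At 24 h the line difference was called for 18 genes in the positive direction and 25 in the negative. PI3 (-5.31, SE 0.347), the transporter SLC15A3 (-4.25), CXCL10 (-4.15), IL4I1 (-3.86, another probe -0.236), MX2 (-3.64), TNF (-3.17, SE 0.422), PTGS2 (-3.10), OAS1 (-2.37, another probe not following) and RELB (-2.12, SE 0.423) responded more in HT29. Positive differences were led by REG4 (3.37), BDNF (2.76, other probes near 0 or lower), PDZK1 (2.55), POU2AF3 (2.45) and F5 (2.43), which had fallen in HT29. The replicate block gave 99 and 124, the slide block 37 and 50, no background correction 29 and 21, leaving out the low-signal array 22 and 44, and only the arrays compared 4 and 4. Without that array MX2, OAS1 and PDZK1 had adjusted p of 0.0981, 0.0793 and 0.0566, and CXCL8 (-2.81, adjusted p = 0.182) and CCL20 (-2.24, adjusted p = 0.268) were called (-4.02 and -3.09, adjusted p of 0.000753 and 0.0264). The interferon response list (median -1.44, 0 positive and 2 negative calls, 19 negative over the list alone, adjusted p = 6.48e-16), the NF-kB list (-0.724, 5 negative, 15 over the list alone with 1 positive, adjusted p = 2.3e-07), antigen presentation (-0.521, adjusted p = 0.00552) and intestinal differentiation (0.657, 1 positive, 5 over the list alone, adjusted p = 0.00315) passed camera. With an estimated correlation these had adjusted p = 0.178, 0.178, 0.225 and 0.178. With the replicate block as well, interferon response, NF-kB and intestinal differentiation had 0.031, 0.031 and 0.00967.

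The TNFa response of mock cells was compared between 2 and 24 h. In HT29 the difference, 24 h minus 2 h, was called for 17 genes, 5 positive and 12 negative. CXCL2 (-3.85, SE 0.516), IL17C (-2.88), CYP4B1 (-2.50, another probe 0.0879), POU2AF3 (-2.21), IL1B (-2.14), the ephrin EFNA1 (-2.14) and NFKBIA (-1.11, SE 0.193, adjusted p = 0.0128) had the lower effect at 24 h. UBD (3.93, SE 0.571), the MHC class II chaperone CD74 (3.08, 1 of 2 other probes not following), IL32 (3.06), the decoy receptor TNFRSF6B (2.73) and PLD6 (1.77, another probe 0.151) had the higher effect. The NF-kB list shifted down (1 positive and 6 negative calls, 3 and 21 over the list alone, median -0.885, adjusted p = 1.99e-11, and 0.0141 with an estimated correlation). Interferon response (1.59, adjusted p = 1.56e-18, then 0.18 with an estimated correlation), antigen presentation (1.07, adjusted p = 6.01e-06, then 0.126), immediate early genes (-0.581, adjusted p = 0.00312, then 0.126) and intestinal differentiation (-0.496, adjusted p = 0.0174, then 0.3) had 0 calls over all genes. The replicate block gave 29 and 30 genes, the slide block 5 and 15, and leaving out the low-signal array 29 and 36, but only the arrays compared 1 and 1. On slides 1 (with the low-signal array) and 2 the NF-kB medians were -1.25 and -0.48 and those of interferon response 1.25 and 1.92.

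In SW480 the same difference was called for 1 gene, PSMB9 (2.33, SE 0.333, adjusted p = 0.0141, another probe 0.332). It was not called without any of 6 of the 11 arrays, with all arrays of both lines in one fit (adjusted p = 0.597) or with only the arrays compared (0.0548). The slide block called 1 and 3 genes, the replicate block 9 and 11, and without background correction 2 were positive and 3 negative. The NF-kB list shifted down with 0 calls over all genes (1 positive and 19 negative over the list alone, median -0.786, adjusted p = 4.38e-30, and 0.00297 with an estimated correlation). Antigen presentation shifted up (0.337, 1 call, 3 over the list alone, adjusted p = 9.26e-08, and 0.00297 with an estimated correlation), as did Wnt targets (0.347, adjusted p = 0.000219, and 0.00932 with an estimated correlation). Interferon response (0.326, adjusted p = 3e-04, then 0.157 with an estimated correlation), immediate early genes (-0.333, adjusted p = 0.00102, then 0.639) and the unfolded protein response (-0.344, adjusted p = 0.00053, then 0.275) had 0 calls. Within slides the medians were -0.384 and -1.06 for NF-kB and 0.295 and 0.492 for antigen presentation.

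**Figure D2:**
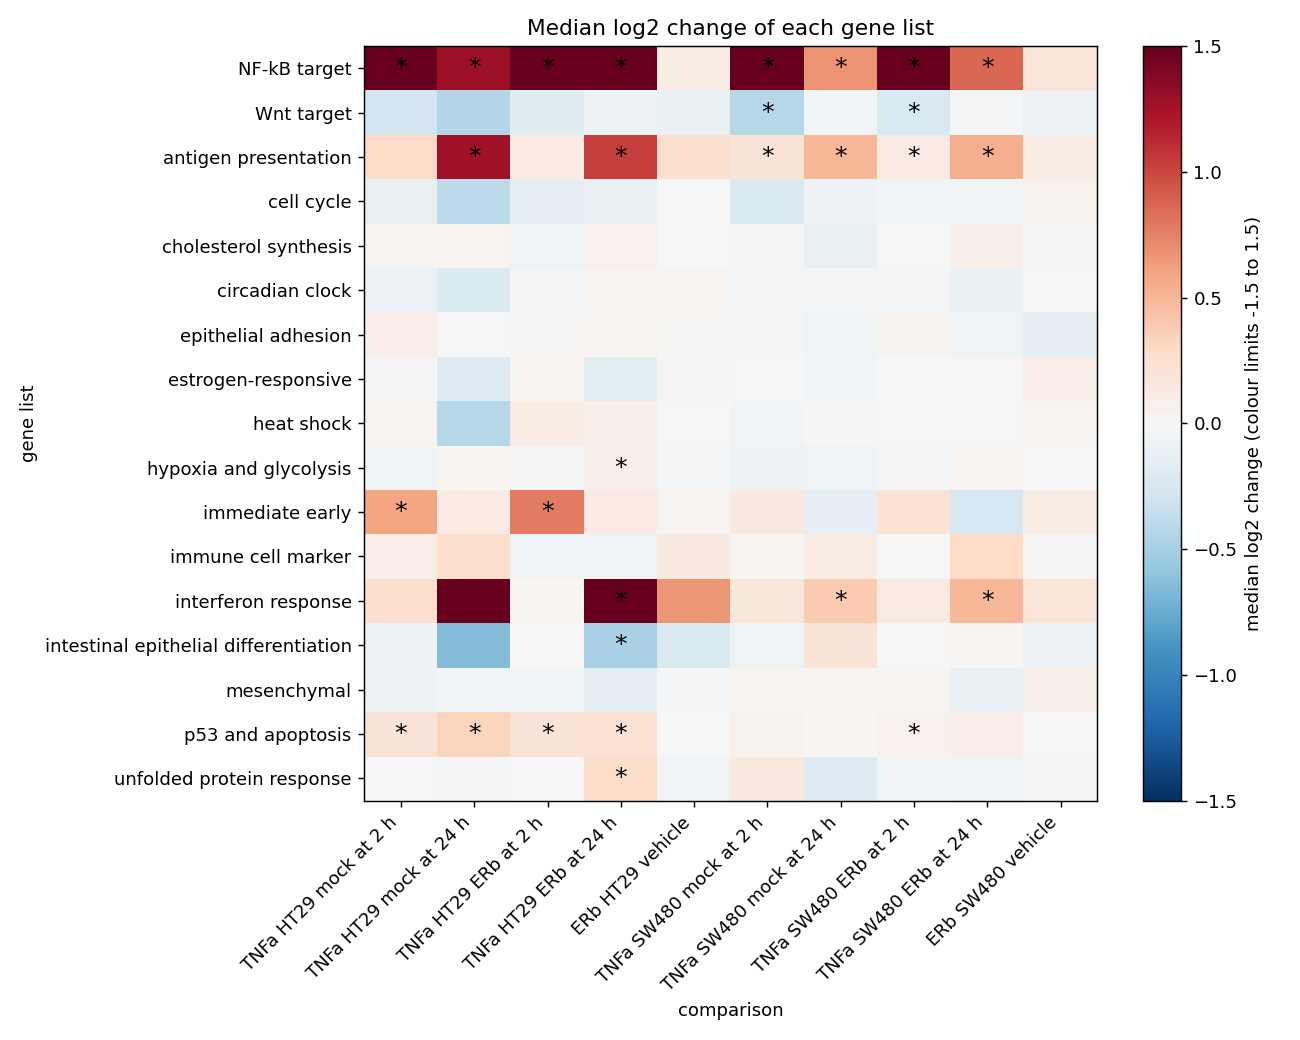
Median log2 change of the measured members of 17 gene lists (vertical) in 10 comparisons (horizontal); colours are limited to ±1.5, and a star marks a camera adjusted p under 0.05 with an estimated correlation. The NF-kB medians run from 0.672 to 2.71 over the 8 TNFa comparisons.

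In HT29 ERb cells TNFa for 2 h raised CCL20 70.7-fold (6.14, SE 0.578), CXCL1 24.1-fold (4.59, SE 0.339), TNFAIP3 24-fold (4.58, SE 0.384), CXCL8 18.1-fold (4.18, SE 0.603) and the chemokine CX3CL1 15.3-fold. CXCL2 rose at least 22.1-fold and TNF at least 14.9-fold. NFKBIA (3.26, SE 0.136), RELB (2.96), NFKB2 (3.33) and ICAM1 (3.61) rose. SOD2 differed by 1.27 (adjusted p = 0.111, but 0.00701 with the replicate block, 0.0122 with the slide as a block and 0.00158 without the low-signal array). Falls were led by FGF9 (-1.69, another probe 0.0838), PRR15L (-1.57) and ZNF792 (2.82-fold). Of the NF-kB list 32 genes rose and 0 fell (38 over the list alone, median 2.37, adjusted p = 1.15e-163, and 3.89e-10 with an estimated correlation). Immediate early genes rose (5 called, 10 over the list alone, median 0.775, adjusted p = 1.9e-17, and 3.23e-05 with an estimated correlation), among them DUSP5 (1.59), FOSL1 (1.45) and JUNB (1.23). So did the p53 and apoptosis list (5 called, 6 over the list alone, median 0.19, adjusted p = 1.28e-08, and 3.23e-05 with an estimated correlation), CDKN1A (2.37, another probe 0.239), PMAIP1 (1.57) and BIK (1.56) among them. The Wnt list lay at -0.185 (0 called, 1 lower over the list alone, adjusted p = 0.0283, then 0.342 with an estimated correlation). In all 93 genes rose and 13 fell (81 and 8 at least 2-fold). The slide block gave 112 and 17, and leaving out the low-signal array 248 and 130. With the replicate block antigen presentation and cell cycle genes also passed camera (both adjusted p = 0.0357).

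At 24 h in HT29 ERb cells LTB rose 56.9-fold (5.83, SE 0.534), CXCL10 54.3-fold (5.76, SE 0.858), UBD 38.8-fold (5.28, SE 0.404), IL32 34.9-fold and PI3 22.2-fold. CCL20 (4.93), CXCL8 (4.71), TNFAIP3 (3.48), RELB (3.15), CXCL1 (2.89), NFKB2 (2.77), NFKBIA (2.18), ICAM1 (1.57), SOD2 (1.57, SE 0.334, adjusted p = 0.0191, another probe 0.0179) and TNF (3.41, at least 7.28-fold) rose. CLEC3A (-3.60, SE 0.614, 12.1-fold lower), REG4 (-2.89) and the transcription factor GATA2 (-2.03) fell. The NF-kB list had 24 rises (33 higher and 1 lower over the list alone, median 1.57, adjusted p = 4.33e-76, and 1.28e-07 with an estimated correlation). Interferon response had 14 of 42 (37 over the list alone, median 2.38, adjusted p = 7.92e-63, and 0.00354 with an estimated correlation), including EPSTI1 (3.62). Antigen presentation had 4 (11 over the list alone, median 1.04, adjusted p = 3.59e-20, and 0.000961 with an estimated correlation), PSMB9 (3.01, another probe 1.64), TAP1 (2.51), TAPBP (1.58, other probes lower) and HLA-F (2.84-fold).

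Other lists moved in HT29 ERb cells at 24 h. The p53 and apoptosis list rose (4 called, 7 over the list alone, median 0.219, adjusted p = 3.54e-08, and 7.5e-05 with an estimated correlation), with TNFSF10 (2.61), CDKN1A (1.85, another probe -0.00246), PMAIP1 (1.58, another probe 0.2) and TNFRSF10B (0.81). Hypoxia and glycolysis genes rose (3 called, median 0.0798, adjusted p = 0.00356, and 0.00771 with an estimated correlation), namely the collagen hydroxylase P4HA2 (1.35), VEGFA (0.99) and the oxidoreductase ERO1A (0.88), the first 2 with 1 probe each that did not follow. The unfolded protein response list lay at 0.27 (0 called, 1 over the list alone, adjusted p = 1.87e-05, and 0.0443 with an estimated correlation), and intestinal differentiation genes at -0.487 (1 fell, 4 over the list alone, adjusted p = 1.57e-05, and 0.0443 with an estimated correlation). Without the low-signal array the last 2 values were 0.103 and 0.23. Immediate early genes had 2 rises (3 over the list alone), DUSP5 (1.52) and NR4A2 (1.13), with a median of 0.128 (adjusted p = 0.00731, then 0.0833 with an estimated correlation). In all 134 genes rose and 24 fell (115 and 18 at least 2-fold). Counts were 217 and 81 with the replicate block, 159 and 33 with the slide block, and 358 and 144 without the low-signal array. Within slides the NF-kB medians were 2.35 and 2.4 at 2 h and 1.65 and 1.5 at 24 h, and those of interferon response at 24 h were 2.36 and 2.38.

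In SW480 ERb cells TNFa for 2 h raised CCL20 19.8-fold (4.31, SE 0.462), TNFAIP3 15.1-fold (3.91), BCL3 14.9-fold (3.90), CXCL1 12-fold (3.58), CXCL8 8.79-fold (3.14) and NFKBIZ 8.75-fold (3.13, another probe 0.0529). TNF rose at least 7.43-fold, and NFKBIA (2.53, SE 0.202), RELB (2.26), NFKB2 (1.94) and ICAM1 (1.73, SE 0.34, adjusted p = 0.0173) rose. SOD2 was not called (0.20). FOXL2, a forkhead transcription factor, was the only called fall (-0.95, another probe -0.229). The NF-kB list had 26 rises and 0 falls (35 over the list alone, median 1.74, adjusted p = 1.03e-128, and 9.72e-07 with an estimated correlation). Wnt targets lay low (-0.231, 0 called, 1 lower over the list alone, adjusted p = 0.000199, and 0.0113 with an estimated correlation), and antigen presentation (0.119, adjusted p = 0.000574, then 0.0375) and p53 and apoptosis (0.0656, 1 called, 2 over the list alone, adjusted p = 0.000229, then 0.0375) lay slightly high. Interferon response (0.125, adjusted p = 0.00954, within slides 0.182 and -0.013), immediate early genes (0.204, adjusted p = 0.000481) and epithelial adhesion (0.0537, adjusted p = 0.0368) passed camera alone. With an estimated correlation these had adjusted p = 0.381, 0.465 and 0.384. In all 53 genes rose and 1 fell (47 and 0 at least 2-fold), with 88 and 9 under the replicate block and 71 and 2 under the slide block, but 29 and 0 with only the arrays compared.

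At 24 h in SW480 ERb cells UBD rose 86.6-fold (6.44, SE 0.29), LTB 27.1-fold (4.76, SE 0.849), IL32 22.1-fold (4.47, SE 0.298) and MMP7, an epithelial matrix metalloproteinase, 9.8-fold (3.29, SE 0.369). CX3CL1 (2.63), CXCL6 (2.61), CCL20 (2.24, SE 0.462), TNFAIP3 (3.16), NFKBIA (1.86), RELB (1.89) and NFKB2 (1.80) rose. CXCL8 and CXCL1 differed by 1.80 (adjusted p = 0.369) and 1.85 (adjusted p = 0.41), and both were called with the replicate block (adjusted p of 0.0295 and 0.0117). ICAM1 (0.59), TNF (0.89) and SOD2 (0.22) were not called. The NF-kB list had 11 rises (26 over the list alone, median 0.866, adjusted p = 6.86e-36, and 0.001 with an estimated correlation). Antigen presentation had 7 (12 over the list alone, median 0.542, adjusted p = 1.69e-21, and 1.86e-05 with an estimated correlation), among them PSMB9 (2.24, another probe 0.466), HLA-B (1.79), TAPBP (1.64, other probes lower) and PSMB8 (1.35, 1 of 3 other probes lower). Interferon response had 0 over all genes and 4 over the list alone (median 0.497, adjusted p = 5.48e-10, and 0.0114 with an estimated correlation). Immune cell markers lay at 0.298 (8 measured, 0 called, 1 over the list alone, adjusted p = 0.0201, then 0.0947 with an estimated correlation), and immediate early genes passed camera only with the replicate block (adjusted p = 0.0483). In all 50 genes rose and 0 fell by limma (38 and 0 at least 2-fold), out of 877 with an unadjusted p under 0.05 (655 with no change). Only the arrays compared gave 17 and 0. Blocking on the replicate gave 160 and 22, and on the slide 74 and 1. Within slides the NF-kB medians were 1.72 and 1.5 at 2 h and 1.09 and 0.746 at 24 h.

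The title's question is addressed by the interaction, the TNFa effect in ERb minus that in mock cells. Most genes that rose in mock cells were also called in ERb cells. In HT29 78 genes rose in both at 2 h and 85 at 24 h (Fisher's exact p = 4.23e-168 and 7.7e-144). Independent lists would share 0.73 and 1.51 (98 and 140 called in mock, 92 and 133 in ERb cells, ESR2 left out). In SW480 43 and 36 rose in both (exact p = 2.09e-107 and 3.7e-85). Independent lists would share 0.198 and 0.179 (50 and 47 called in mock, 52 and 50 in ERb cells). Of the falls in HT29 mock cells, 9 of 12 at 2 h and 17 of 55 at 24 h were also called in ERb cells. By limma the interaction called 1 gene in HT29 at 2 h, ESR2 itself (3.46, SE 0.309, adjusted p = 1.04e-05, within slides 3.93 and 2.53). It called 0 genes in HT29 at 24 h and in SW480 at 2 and 24 h. There 216, 182 and 252 genes had an unadjusted p under 0.05, against 96 in HT29 at 2 h. The replicate block gave 315, 326, 580 and 122. All are below the 618 (HT29) and 655 (SW480) of no change, so a lack of effect is not shown. The ESR2 interaction was 1.75 in HT29 at 24 h (adjusted p = 0.232). It was called there without the low-signal array (1.92, adjusted p = 0.0272), with the authors' values (1.30, adjusted p = 0.0323) and with all arrays of both lines in one fit (adjusted p = 0.0234). In SW480 it was 1.64 at 2 h (adjusted p = 0.71) and 0.87 at 24 h (adjusted p = 1). The second ESR2 probe called the HT29 difference at 24 h (1.52, adjusted p = 0.0361).

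Of the NF-kB panel, BIRC3 and IL6 were not tested in any comparison, and none of the other 10 genes was called in an interaction. The difference for NFKBIA in HT29 was -0.44 at 2 h (SE 0.193, adjusted p = 1) and -0.41 at 24 h (adjusted p = 0.677). RELB in SW480 at 2 h differed by -0.59 (SE 0.276, adjusted p = 1). Of the 46 NF-kB targets at 2 h, 30 had a smaller response in ERb cells in HT29 (median difference -0.0841, range -0.869 to 0.592) and 31 in SW480 (-0.206, range -0.863 to 0.582). The median SE of a single gene was 0.474 and 0.41. At 24 h 22 were smaller in HT29 (median 0.0345, range -1.52 to 1.35) and 16 in SW480 (0.102, range -0.624 to 2.04). The list's interaction had an adjusted p of 0.291 in HT29 at 2 h, 0.848 in HT29 at 24 h, where camera pointed down against a positive median, and 0.232 in SW480 at 24 h. In SW480 at 2 h it passed camera (adjusted p = 0.0314, and 0.0122 with the replicate block), but had 0.974 with an estimated correlation and 0.992 by fry. Within slides that median was -0.16 and -0.212 in SW480 at 2 h (slide block adjusted p = 0.00469), -0.16 and -0.0344 in HT29 at 2 h, 0.401 and -0.0703 in HT29 at 24 h, and 0.107 and 0.0872 in SW480 at 24 h. Genes that rose with TNFa in mock cells of the other line passed in 0 interactions (lowest adjusted p of 0.0616), except with the replicate block in HT29 at 24 h (-0.411, adjusted p = 0.0316).

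**Figure D3:**
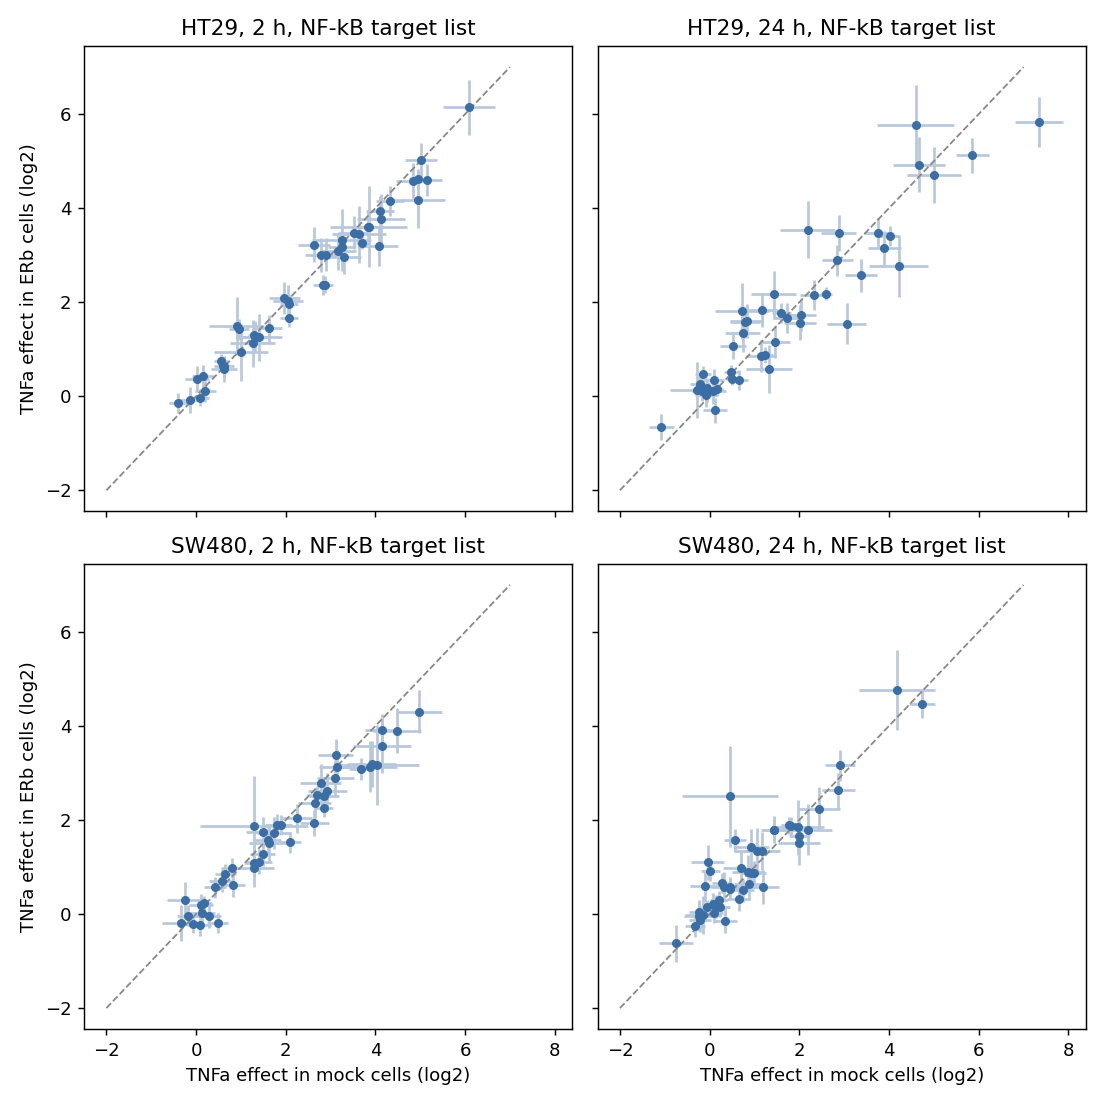
TNFa effect (log2) on each of 46 NF-kB targets in mock cells (horizontal) and ERb cells (vertical), 1 panel per line and time, with SE bars and a dashed line of equality. Of the 46 points, 30 lie under the line in HT29 and 31 in SW480 at 2 h, with 22 and 16 at 24 h.

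The ERb construct was compared with mock in vehicle cells over both times. In HT29 (6 arrays against 6) the largest differences were in the GAGE family of cancer-testis antigens, near-identical gene copies that probes can hardly tell apart, so single members are uncertain. All 9 tested members were higher in ERb cells (0.694 to 3.42, every scaling alike in sign) and 8 were called, such as GAGE12G (3.42, SE 0.212, 10.7-fold), GAGE12C (3.18, 9.05-fold), GAGE4 (3.10), GAGE12J (2.92, at least 6.27-fold) and GAGE12F (2.51, at least 3.72-fold). In SW480 5 members were tested, all with positive differences (0.143 to 0.326) and 0 called. TGM2, which encodes transglutaminase 2, was 4.55-fold higher (2.19, SE 0.252, adjusted p = 8.94e-05), and LOXL4, a lysyl oxidase of the matrix, 4.07-fold higher (2.02, SE 0.256, adjusted p = 0.000284). In all 22 genes were higher and 1 lower (17 and 0 at least 2-fold). The lower gene, named here after its value was seen, was the forkhead factor FOXA2 (-0.63, SE 0.122, adjusted p = 0.0308), whose arrays overlapped between constructs. The NF-kB genes NFKBIA (0.40, SE 0.0964, adjusted p = 0.194) and CXCL8 (1.08, adjusted p = 1) were not called. Without the low-signal array, which is no vehicle array and acts through the shared spread, they had adjusted p of 0.0272 and 0.000739.

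Every list had 0 genes called over all genes in HT29 ERb cells by limma, yet 4 lists passed camera. Interferon response lay high, with 42 of 42 genes positive (median 0.66, adjusted p = 1.7e-33), antigen presentation (0.241, 2 over the list alone, adjusted p = 7.19e-09) and NF-kB (0.108, 2 over the list alone, adjusted p = 8.35e-06) lay high, and intestinal differentiation low (-0.221, adjusted p = 5.02e-06). Each had adjusted p = 0.0565 with an estimated correlation and 0.207 by fry. With the replicate block and an estimated correlation, interferon response had 0.00605 and antigen presentation and intestinal differentiation 0.00331, and mesenchymal genes passed camera (adjusted p = 0.00911). Within slides the medians were 0.654 and 0.765 for interferon response, 0.182 and 0.319 for antigen presentation, 0.163 and 0.0482 for NF-kB, and -0.249 and -0.117 for intestinal differentiation. The replicate block called 55 genes higher and 5 lower, the slide block 27 and 3, and leaving out the low-signal array 48 and 6. Called genes had median sizes of 1.2 and 1.22 within slides.

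In SW480 (6 arrays against 5) most called genes were higher in ERb cells. CST1, a secreted cystatin, was at least 42.1-fold higher (5.96, SE 0.552, adjusted p = 1.72e-06), TGM2 25-fold (4.64, SE 0.457), the IGF-binding protein gene IGFBP7 19.2-fold (4.26, SE 0.35), the G protein subunit gene GNG11 at least 15.5-fold (4.25), ANKRD1 at least 13.7-fold (3.98, SE 0.269), the vitamin D hydroxylase CYP24A1 at least 8.2-fold (3.51) and WNT5A at least 5.65-fold (3.21). IGFBP2 was 4.22-fold lower (-2.08, SE 0.17, adjusted p = 4.52e-07), with the adhesion molecules ALCAM (-1.39) and CD24 (-0.71) and the carboxypeptidase CPVL (-1.35). Called list members included the Wnt inhibitor APCDD1 (2.20, SE 0.191), KRT13 (2.12, at least 2.77-fold), the matricellular gene CCN1 (2.46, SE 0.577, adjusted p = 0.0489), CDKN1A (1.93, another probe 0.0777), smooth muscle actin ACTA2 (1.74) and PSMB9 (1.13, another probe 0.207). In all 103 genes were higher and 8 lower (73 and 3 at least 2-fold). The replicate block gave 239 and 38, the slide block 175 and 13, and only the arrays compared 69 and 4. Within slides the called genes had median sizes of 1.11 and 1.45. All had the same sign in both, but for the 90 of 111 whose arrays did not overlap that is fixed in advance.

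List shifts in SW480 ERb cells were small, and 0 held with an estimated correlation. NF-kB (0.178, adjusted p = 0.00413), interferon response (0.177, 1 over the list alone, adjusted p = 0.00607), antigen presentation (0.111, 1 called, 4 over the list alone, adjusted p = 0.0053) and epithelial adhesion (-0.131, adjusted p = 0.0418) passed camera. With an estimated correlation they had adjusted p = 0.541, 0.485, 0.253 and 0.485. With the replicate block immediate early genes (adjusted p = 0.0411) and cell cycle genes (adjusted p = 0.0212) passed as well, and with the slide block immediate early genes did (0.139, adjusted p = 0.00674). Within slides the NF-kB medians were 0.12 and 0.268 and those of interferon response 0.231 and 0.158.

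**Figure D4:**
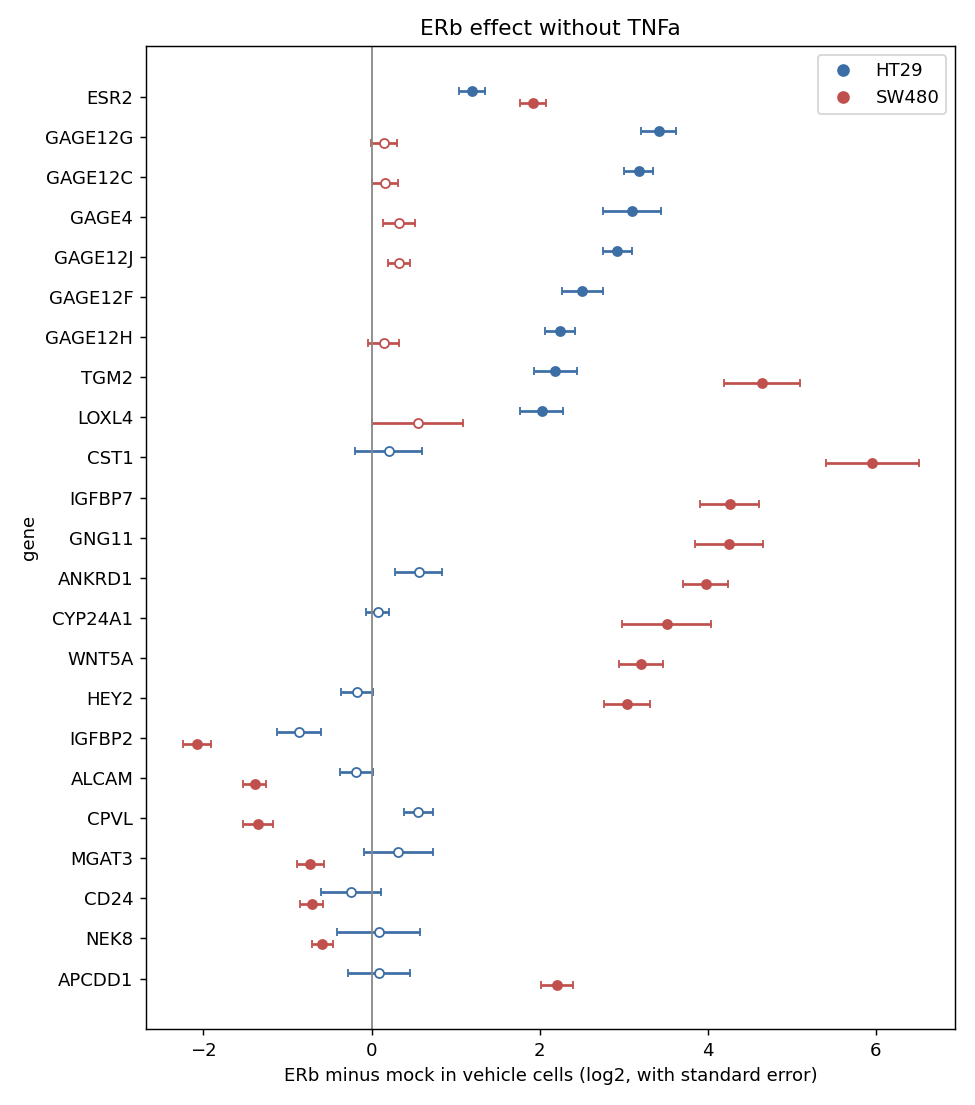
ERb minus mock in vehicle cells (log2, with SE) for named genes in HT29 and SW480; open points were not called and missing points not tested in that line. TGM2 is called in both lines (2.19 and 4.64), and GAGE12G (3.42) leads in HT29 and CST1 (5.96) in SW480.

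Besides ESR2, the lines shared 1 called ERb difference, TGM2. Among genes tested in both, 16 called in HT29 and 68 in SW480 were higher (0.0942 for independent lists, Fisher's exact test p = 0.0902). Without the low-signal array 3 were shared, KLRC2, NT5E and TGM2 (exact p = 0.00153), the first 2 named after their calls were seen. The difference of the ERb effect between lines was called for 67 genes, 50 positive (SW480 minus HT29) and 17 negative. It was positive for CST1 (5.75, SE 0.702), GNG11 (4.31), IGFBP7 (4.13, SE 0.372), CYP24A1 (3.44), ANKRD1 (3.42), APCDD1 (2.11) and CDKN1A (1.88, another probe 0.0698), and negative for GAGE12G (-3.27, SE 0.267), GAGE12C (-3.02), GAGE4 (-2.77), GAGE12J (-2.60) and GAGE12F (-2.34). For ESR2 itself it was 0.72 (SE 0.223, adjusted p = 0.279). Interferon response (-0.581, adjusted p = 2.55e-12) and antigen presentation (-0.171, adjusted p = 0.0468) were lower in SW480 by camera, but both had 0.466 with an estimated correlation. The replicate block gave 112 and 38 genes, with the Wnt list passing camera (adjusted p = 0.0213), the slide block 83 and 21, and leaving out the low-signal array 81 and 22.

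Of the lists, 5 passed camera in no comparison here, apart from mesenchymal genes with the replicate block. Their lowest adjusted p was 0.134 (estrogen-responsive), 0.0541 (mesenchymal), 0.115 (cholesterol synthesis), 0.493 (circadian clock) and 0.0999 (heat shock).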

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

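The 3 tests of the ESR2 signal, that of uniform dimming, the comparison with single arrays of each line, the score with the low-signal array kept, the splits between same-numbered arrays and the comparison of vehicle cells between times were chosen only after results were seen; the other tests were planned.

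The ESR2 signal rose with TNFa in cells that carried the ERb construct, and in HT29 at 2 h the interaction called 1 gene, ESR2 (3.46). An own ESR2 gene or a cross-hybridising transcript induced by TNFa is argued against, since the largest change in mock cells at 2 h, over both probes and both lines, was 0.0673 (SE 0.219). An early response of the introduced gene's transcript needs a smaller TNFa effect at 24 h than at 2 h, and the difference in ERb cells was -1.65 (SE 0.309) in HT29 and -0.771 (SE 0.299) in SW480. A candidate explanation is that the construct's expression itself follows TNFa, so that ERb and mock cells with TNFa also differ in how much ESR2 transcript they hold. The construct's promoter is not given in the sources used here, and this was found and tested on the same data.

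The low-signal HT29 array (mock, TNFa, 24 h) had an EEF1A1 intensity of 2842 against 19943 to 28317 on the other HT29 arrays. GAPDH, at 14204, was not low (7021 to 14131). A vehicle sample under the wrong label is argued against. This rests on 157 genes called in HT29 ERb cells at 24 h. Over them the array lay 0.972 (spread 0.0589) of the way from the mock vehicle mean to the rest of its group. Uniform dimming is argued against, because the log2 ratio of its signal to the other arrays, over the 1000 brightest probes, had an interquartile range 8.8 times that of the widest other array (3.03 against 0.137 to 0.344 for 23 arrays). A sample of the other line is argued against: 86.5% of the 200 genes that differ most between lines lay nearer the HT29 mean, short of the 90% set beforehand but far from the 23 SW480 arrays (at most 1.5%; other HT29 arrays at least 97.5%), and of the 111 higher in HT29 87 did (at most 3 in SW480). A loss that differs between transcripts, such as partly degraded RNA, or an admixture may remain and was not tested.

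Genes differed between ERb and mock cells without TNFa, and besides ESR2 only 1 called gene was shared by the lines. A response to ERb common to both lines needs each line's genes to move the same way in the other: 17 genes called in HT29 moved by a signed mean of 0.584 (SE 0.09) in SW480 against 1.71 in HT29, and 76 genes called in SW480 by 0.126 (SE 0.0483) in HT29 against 1.53. For the SW480 genes a response of like size is argued against, since the value plus 2 SE (0.223) is under the limit set beforehand (0.382), but the value also met the mark set in favour, above 0 by over 2 SE (43 of 76 went the same way, 0.0987 without TGM2), so a small one stays open, as does that of the HT29 genes (16 of 17, of which 5 are GAGE copies, 0.331 without TGM2). A response that follows the amount of ESR2 transcript is argued against in HT29, as the 18 genes called at 2 h without the low-signal array had a signed mean interaction of -0.0635 (SE 0.183) at 24 h against an ERb effect of 1.78, and the 7 called with it kept -0.151 (SE 0.329) against 2.76, although 7 of the 18 and 6 of the 7 are GAGE copies. What may remain is a difference between the mock and ERb cell populations that is unrelated to ERb, which nothing in the design separates from ERb.

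Other splits of the same arrays were fitted for counts with at least 3 arrays in every group, so not where SW480 mock vehicle cells at 2 h are a group of their own. For TNFa against vehicle within 1 line, construct and time there are only 10 splits, too few for a share under 0.05. The real split alone reached its count, 1 of 10 each time, and the highest other gave 0 against 110 and 195 in HT29 mock cells at 2 and 24 h, 1 against 106 and 0 against 158 in HT29 ERb cells, 1 against 47 in SW480 mock cells at 24 h, and 4 against 54 and 0 against 50 in SW480 ERb cells. For ERb against mock with vehicle, splits between same-numbered arrays argue against array spread alone, not chance between cell populations. In HT29 (23 genes, highest other 0) and SW480 (111 genes, highest other 10) 1 of 32 reached the count. For the line difference 2 of 100 did (67 genes, highest other 76). Splits that ignore the numbers gave 1 of 100 (highest other 0), 2 of 100 and 1 of 100 (highest other 58). In SW480 1 of these called 583 genes; it gathers all 4 replicate 3 arrays and 5 of its 6 arrays lie on slide 4, which points to a structure by replicate and slide. With these as a block the real split called 277 and 188 genes.

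For the differences of TNFa effects the splits settle nothing about chance. For the interactions at 24 h in HT29 and SW480 the real count is 0, which 100 of 100 splits reach by construction (highest other 520 and 120). As many genes as the real split were called by 9 of 100 splits for the HT29 interaction at 2 h (1 gene, highest other 244), by 12 of 100 for the time difference in HT29 (17 genes, highest other 254) and by 7 of 100 for the line difference at 24 h (43 genes, highest other 215). Each of these highest splits exchanges all treatment labels on 1 side, so that the difference becomes a sum of 2 TNFa effects and a high count is built in. Splits that part fewer pairs gave at most 126 and 5 for the interactions at 24 h, and 1, 69 and 153 for the others.

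Some TNFa effects differed between times by the test of the difference itself. In HT29 mock cells 17 genes did, among them UBD (3.93), CD74 (3.08), IL32 (3.06), TNFRSF6B (2.73) and PLD6 (1.77) with the more positive effect at 24 h, and CXCL2 (-3.85), IL17C (-2.88), CYP4B1 (-2.50), POU2AF3 (-2.21), IL1B (-2.14), EFNA1 (-2.14) and NFKBIA (-1.11) with the more positive effect at 2 h. In SW480 mock cells 1 gene did, PSMB9 (2.33).

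Others differed between lines, as SW480 minus HT29. At 2 h 12 genes did, among them UBD (2.63), NFKBIZ (2.56), PRR15L (2.32), SLITRK6 (1.72), PTGS2 (-3.89), FAM43A (-3.33), PI3 (-3.20), IER3 (-2.46) and IL1B (-2.05). At 24 h 43 genes did, among them REG4 (3.37), BDNF (2.76), PDZK1 (2.55), POU2AF3 (2.45), F5 (2.43), PI3 (-5.31), SLC15A3 (-4.25), CXCL10 (-4.15), IL4I1 (-3.86), MX2 (-3.64), TNF (-3.17), PTGS2 (-3.10), OAS1 (-2.37) and RELB (-2.12). The ERb effect differed for 67 genes, among them CST1 (5.75), GNG11 (4.31), IGFBP7 (4.13), CYP24A1 (3.44), ANKRD1 (3.42), APCDD1 (2.11), CDKN1A (1.88), GAGE12G (-3.27), GAGE12C (-3.02), GAGE4 (-2.77), GAGE12J (-2.60) and GAGE12F (-2.34).

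Probes with no gene symbol in the annotation used here, which entered no comparison above, also responded to TNFa in mock cells. In HT29, of 6586 such probes, 26 were called at 2 h (23 higher) and 34 at 24 h (25 higher), and in SW480, of 7312, 7 were called at each time, all higher.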

How the results depend on the processing

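Leaving out the low-signal array where it is not among the arrays compared, or with the replicate block, was chosen after seeing the data, as was the comparison of vehicle cells between times; the other alternatives were planned, leaving out each array compared in turn included, and the cause of a change was not tested unless stated. Of 7362 alternative values for 391 named gene results, 6469 kept their direction and their side of the threshold, 812 lost the call, 77 gained one and 4 reversed, all 4 among genes not called: SOD2 in SW480 mock cells at 2 h (-0.0484 without TNFa replicate 1, -0.278 without vehicle replicate 3, highest 0.513) and at 24 h (-0.0628 without vehicle replicate 2, highest 0.196), and ICAM1 in SW480 mock cells at 24 h (0.0989 without TNFa replicate 1, lowest -0.366). Of the lost calls 573 came from leaving out 1 of the arrays and 98 from fitting only the arrays compared, which have fewer samples to estimate the spread. Signal over background limits ESR2 in mock cells and the genes given as at least a fold.

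Counts of called genes moved by more than 1.5 times as follows. With the replicate block (paired by number) they were 441 and 298 for TNFa in HT29 mock and ERb cells at 24 h, 83 and 130 in SW480 mock and 97 and 182 in SW480 ERb cells at 2 and 24 h, 60 and 277 for ERb in HT29 and SW480, 59 and 20 for the time difference in HT29 and SW480, 223 for the line difference at 24 h and 150 for that of ERb. The replicate block changed 14 of 391 named gene results, all gained calls. Those not given elsewhere were ICAM1 for ERb in SW480 (adjusted p = 0.0204), the line difference at 24 h (0.00546) and the time difference in SW480 (0.0335), NFKB2 in the line difference at 24 h (0.024), CXCL1 in the time difference in HT29 (0.0499) and RELB in SW480 vehicle cells between times (0.0122). It also changed the list calls named beside the results. With it p53 and apoptosis (adjusted p = 0.0308) and Wnt (0.0412) also passed camera in the line difference at 2 h, and it changed no other call of a named gene or, at the preset correlation, of a list. Without the low-signal array counts were 484 and 338 in HT29 mock cells and 378 and 502 in HT29 ERb cells at 2 and 24 h, 54 for ERb in HT29, 1 for the HT29 interaction at 24 h, 65 for the time difference in HT29, 66 for the line difference at 24 h and 103 for that of ERb. Calls gained without it and not given elsewhere were ICAM1 in the line difference at 2 h (adjusted p = 0.0455), CXCL1 (0.0285) and ICAM1 (0.00224) in the HT29 time difference, and CCL20 (0.0409) and ESR2 (0.0142) in HT29 vehicle cells between times. Adding the replicate block, they were 971, 751, 702, 1179, 263, 1, 353, 278 and 275 in the same order, and 81 for the line difference at 2 h. In the line difference at 24 h, lists of immediate early genes (0.00213), the unfolded protein response (0.000529), hypoxia (0.0104) and immune cell markers (0.0388) passed camera without that array, as did the same lists in HT29 mock cells at 24 h (0.0252, 0.0326, 0.0193 and 0.0243), and Wnt in the line difference at 2 h (0.0468), while Wnt in HT29 ERb cells at 2 h no longer did (0.0606).

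With only the arrays compared, counts were 194 and 6 in HT29 mock and 226 and 258 in HT29 ERb cells at 2 and 24 h, 14 in SW480 mock cells at 2 h, 29 and 17 in SW480 ERb cells, 44 and 73 for ERb in HT29 and SW480, 2 for the time difference in HT29 and 8 for the line difference at 24 h. With all arrays of both lines in one fit they were 1016 and 259 in HT29 mock and ERb cells at 24 h, 38 for ERb in HT29, 1 for the HT29 interaction at 24 h, 38 for the time difference in HT29 and 0 in SW480. Testing every probe gave 35 for ERb in HT29, 2 for the HT29 interaction at 2 h (both of ESR2) and 27 for the time difference in HT29. No background correction gave 26 and 5 for the time differences in HT29 and SW480. The authors' values gave 1 for the HT29 interaction at 24 h, 2 for the time difference in SW480 and 19 for the line difference at 2 h. The slide as a block gave 188 for ERb in SW480, 4 for the time difference in SW480, 87 for the line difference at 24 h and 104 for that of ERb. At an adjusted p under 0.01 the overlap of lines at 24 h was 14 genes.

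The NF-kB list lost its call with an estimated correlation and by fry, tests that allow for correlated genes or compare no other genes, for ERb in HT29 (median 0.108, adjusted p = 0.0565 and 0.207), ERb in SW480 (0.178, adjusted p = 0.541 and 0.415) and the SW480 interaction at 2 h (-0.206, adjusted p = 0.974 and 0.992). The latter also lost it without background correction (-0.1, adjusted p = 0.0815), with the authors' values (-0.143, 0.0745), with no filter (-0.195, 0.0511) and with all arrays in one fit (-0.206, 0.0816). The median of the HT29 interaction at 24 h, not called, reversed to -0.0262 without the low-signal array, to -0.0711 with the replicate block as well, and to -0.0909 and -0.105 without ERb TNFa replicate 1 or ERb vehicle replicate 2. That of the SW480 interaction at 24 h reversed to -0.0573 without ERb vehicle replicate 1 and was called without mock vehicle replicate 1 (0.174, adjusted p = 0.0364), mock TNFa replicate 1 (0.0974, 0.0249) or ERb vehicle replicate 3 (0.22, 0.000263).

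Leaving out each array in turn, counts ranged from 74 to 90 and 88 to 4312 in HT29 mock cells at 2 and 24 h, 75 to 91 and 72 to 123 in HT29 ERb cells, 35 to 52 and 22 to 41 in SW480 mock cells, and 37 to 54 and 23 to 47 in SW480 ERb cells. They ranged from 21 to 24 for ERb in HT29, 65 to 135 in SW480, 1 to 1 and 0 to 1 for the HT29 interactions, 0 to 0 for both SW480 interactions, 11 to 65 and 0 to 2 for the time differences in HT29 and SW480, and 9 to 13, 21 to 2618 and 52 to 88 for the line differences at 2 h, at 24 h and of ERb. NF-kB list medians ranged from -0.124 to -0.0333 and -0.105 to 0.102 for the HT29 interactions, -0.309 to -0.0515 and -0.0573 to 0.22 for the SW480 interactions, 0.0592 to 0.132 for ERb in HT29 and 0.0554 to 0.269 in SW480.

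Arrays that moved a count by more than 1.5 times (count without them) were as follows. In HT29 mock cells at 24 h they were vehicle replicates 1 (117), 2 (88) and 3 (104) and TNFa replicates 1 (338), 2 (4312) and 3 (3914); in the last pair the low-signal array is 1 of 2 left. In HT29 ERb cells at 24 h they were TNFa replicates 1 (78) and 2 (98) and vehicle replicates 2 (72) and 3 (86), in SW480 mock cells at 24 h vehicle replicates 1 (24) and 2 (31) and TNFa replicates 1 (22) and 3 (24), and in SW480 ERb cells at 24 h vehicle replicates 1 (23) and 2 (26) and TNFa replicate 3 (26). For ERb in SW480 it was mock vehicle 2 h replicate 1 (65), whose group then had 1 array, assumed to vary like the others. For the line difference at 24 h they were HT29 TNFa replicates 1 (66), 2 (2618) and 3 (2375), HT29 vehicle replicate 2 (21), and SW480 TNFa replicates 1, 2 and 3 and vehicle replicate 3 (27 each). For the time difference in HT29 they were TNFa 24 h replicates 1 (65) and 3 (27) and TNFa 2 h replicate 2 (11). That of SW480 fell to 0 without any of 6 of 11 arrays (vehicle 2 h replicates 1 and 3, vehicle 24 h replicates 1 and 2, TNFa 2 h replicate 2, TNFa 24 h replicate 3) and rose to 2 without TNFa 2 h or 24 h replicate 1. The NF-kB list in the SW480 interaction at 2 h was not called without mock vehicle replicate 1 (-0.0727), mock TNFa replicates 2 (-0.162) or 3 (-0.158), ERb TNFa replicate 1 (-0.0827), or ERb vehicle replicates 2 (-0.147) or 3 (-0.0515), and that of ERb in SW480 not without mock vehicle 2 h replicate 1 (0.066), ERb vehicle 2 h replicate 3 (0.102) or ERb vehicle 24 h replicate 3 (0.0554).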

Other observations

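The comparison of vehicle cells between times and its tests were chosen only after the data were seen. Without TNFa, mock and ERb cells together differed between 24 and 2 h. In HT29 (6 arrays against 6) the trefoil factor gene TFF1 was 7.87-fold lower at 24 h (-2.98, SE 0.527, adjusted p = 0.0093), and the matricellular genes CCN2 (-2.24, SE 0.271, adjusted p = 0.000302) and CCN1 (-1.39), CXCL8 (-1.94) and the immediate early gene FOSB (-1.92) were lower too. The transcription factor MYB (1.15, adjusted p = 0.000298), the mTOR inhibitor DDIT4 (1.18) and the ephrin receptor EPHB3 (0.89) were higher. In SW480 (6 against 5) DDIT4 was 7.17-fold higher at 24 h (2.84, SE 0.38, adjusted p = 0.000186), with the transcription factors NFE2 (2.34) and BCL6 (2.16). FOSB (-3.10, adjusted p = 0.000442), the metallothionein MT1G (-3.57, SE 1.06, adjusted p = 0.0495) and FOSL1 (-2.06) were lower.

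In HT29 45 genes were higher and 52 lower at 24 h, and in SW480 434 and 430. The counts in all were 97 and 864, with 308 and 2410 under the replicate block, 361 and 1317 under the slide block, 193 and 525 with all arrays in one fit, 1044 and 521 with only the arrays compared, and 1231 in HT29 without the low-signal array, which enters only through the spread. Leaving out each array in turn gave 30 to 83 in HT29, under 97 each time and moved by over 1.5 times without mock 2 h replicate 3 (30), mock 24 h replicates 1 (46) and 2 (51), ERb 2 h replicates 1 (60) and 3 (31) or any ERb 24 h replicate (36, 56 and 57), and 549 to 891 in SW480 (549 without mock 2 h replicate 1, 566 without ERb 24 h replicate 3). Of 26 immediate early genes 7 were lower in HT29 and 0 higher (7 and 1 adjusted over the list alone, median -0.237, adjusted p = 1.44e-06, and 0.0169 with an estimated correlation, 0.127 without the low-signal array). Of 27 in SW480 8 were lower and 2 higher (14 and 2 over the list alone, median -0.4, adjusted p = 6.31e-06, then 0.977 with an estimated correlation). Within slides these medians were -0.127 and -0.263 in HT29 and -0.632 and -0.428 in SW480. Interferon response genes in HT29 had 0 calls by limma (10 lower over the list alone) with a median of -0.88 (adjusted p = 4.9e-21, then 0.135 with an estimated correlation, within slides -0.304 and -1.25). In HT29 the p53 and apoptosis list lay at -0.121 (1 lower, adjusted p = 0.00622, and 0.021 with an estimated correlation), and NF-kB (-0.0101, adjusted p = 0.027), antigen presentation (-0.239, adjusted p = 0.00622) and hypoxia (-0.123, adjusted p = 0.027) passed camera only at the preset correlation (adjusted p = 0.351, 0.351 and 0.0528 with an estimated correlation). Under the replicate block Wnt (adjusted p = 0.0226) and intestinal differentiation (0.0181) passed in HT29 and cell cycle genes (0.0475) in SW480. Called genes kept their sign within both slides, with median sizes of 0.849 and 0.943 in HT29 and 0.551 and 0.692 in SW480. Array spread alone is argued against, as only the real one of 32 splits between same-numbered arrays reached the counts. The highest other gave 0 in HT29 and 168 in SW480 (1 of 100 and the same highest when numbers are ignored). The latter mirrors the real split closely, with 5 of the 6 arrays placed at 24 h taken at 2 h. Slide partly follows time, as replicate 2 lay on the first slide of its line at 2 h and on the second at 24 h.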
